A study of Arabidopsis thaliana with 18 samples.

How the data were processed

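The data were 18 Affymetrix ATH1 arrays of Arabidopsis thaliana accession Mt-0, with total RNA as the extracted molecule and biotin as the label. Per the labels, 9 arrays came from plants treated with 0.02% silwet, a surfactant used as carrier, and 9 from plants that received the same surfactant together with SA at 0.30 mM. SA is read here as salicylic acid, a plant defence hormone. The array titles carry replicate numbers 1 to 3, each on 3 arrays of either treatment, and serial numbers. Runs of 3 consecutive serial numbers, each holding replicates 1, 2 and 3, gave 3 serial sets per treatment, called sets 1, 2 and 3 here. The labels used here do not say what distinguishes the sets, nor do they give tissue, plant age or harvest time. Nothing in them says that the arrays came from separately grown plants, so the p-values measure the spread between these arrays, which may be partly technical.

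The deposited values are MAS5 probe set signals on a linear intensity scale, per the submitters' processing notes, which name MAS5 without a version. The intensity table showed that the authors had scaled each array, since the mean after trimming 2% at either end was 100.01 on every array to within rounding. Genome build and annotation are not given in the sources used here. Median signal per array ran from 27.5 to 37.3. For arrays, the number of arrays limits the precision.

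Probe sets were named from the platform's probe table, updated through gene identifiers in RefSeq's TAIR10.1 table, from which no coordinates were taken. Of 22810 probe sets, 64 were controls, 13513 had exactly 1 gene, 503 had several and 8730 Arabidopsis probe sets were unnamed here. Of the 13513, 13436 matched the RefSeq table and 11933 carried only a locus code as name. No gene was named from a probe set with several genes.

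Signals were transformed as log2(signal + 16) without further normalization, so fold changes understate those of weakly expressed genes. The Arabidopsis probe sets in the upper 60% by mean log2 over all arrays were tested, which left 13647. SA was compared with silwet by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This pooled comparison of 9 arrays with 9, without a block, was the main design, fixed before the data were examined, as were 18 gene lists, the rule for named genes and most alternatives. Gene lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. The log2 ratio of 3′ to 5′ signal of the actin, GAPDH and ubiquitin control probe sets was compared by an exact permutation test over all 48620 arrangements.

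After the pooled result and the correlations between arrays had been seen, a model of the 6 cells of treatment by serial set was added, with 3 arrays per cell and 12 residual degrees of freedom. It gives SA minus silwet within each set, the difference between set 1 and the mean of sets 2 and 3, and an F test of all differences between sets. Each of these was adjusted separately over 13647 probe sets. The serial sets themselves had been fixed beforehand, but only as a block.

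Of 302 genes in the 18 lists, the probe table named 36, and 5 lists had none named, including the pathogenesis-related genes and the TGA factors. The lists can therefore not be judged as whole groups, and the genes that the naming rule always included are not reported here. Gene families defined by symbol alone were added after the probe table had been read and before any difference between treatments was computed. Together 26 lists had enough members. Of the lists fixed beforehand, only that of endoplasmic reticulum folding and secretion was among them, so the others had no camera test.

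Genes were named by rule: the 12 probe sets with the largest increase and the 12 with the largest decrease among those past the threshold, with exactly 1 gene and the same sign in all 3 replicate numbers, and up to 4 members per list with the smallest adjusted p. As the pooled comparison called no probe set, the rule was applied to set 1. Family members were named by the same rule.

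Same-numbered SA and silwet arrays of a set deviated together from their cell means, with correlations across probe sets from 0.129 to 0.770 over the 9 pairs. From the treatment means the correlations ran from 0.0106 to 0.797, so 1 of these pairs was uncorrelated. Of the 9 SA arrays, 6 correlated best with the silwet array of their own pair. The titles carry a second number, whose meaning the labels do not give. In its order the arrays of each replicate number lie together, and within them each SA array directly follows the silwet array of its set. The titles thus tie the same pairs, without saying that a pair or a replicate number shares a batch or a day. The fit counts with and without it had already been computed when this check was made.

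The fits were tested on simulated arrays built from the real means and spreads of the 13647 probe sets, with a few of them changed by known amounts. For set 1, 92.4% of changes of 2 log2 units, 71.6% of changes of 1 unit and 1.49% of changes of 0.5 units were recovered. The real set 1 fit called 1753 probe sets, far more than were changed in the simulation. With more changed probe sets the adjusted threshold is easier to pass, so the set 1 shares do not give the sensitivity of the real fit. For the pooled comparison, the shares were 97.0%, 95.5% and 43.3%. These pooled shares do not cover an effect that differs between sets, which stays in the error of the real pooled fit. There, AT3G13610 at 1.40 ± 0.59 and UGT76B1 at 1.34 ± 0.83 (log2 difference and SE) were not called (limma adjusted p = 0.9997 each). The shares are therefore no measure of how many such effects the pooled comparison would find. Alternatives covered the pseudocount, scaling, filter, variance trend, array weights, blocks, averaging, left-out arrays and ambiguous probe sets. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for joins and plots.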

Results

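The transcript levels of Mt-0 plants that received SA at 0.30 mM, with the surfactant silwet as carrier, were measured on 9 ATH1 arrays and set against 9 arrays of plants that received silwet alone. The comparison asks which transcripts differ after SA. MAS5 signals had been scaled to a common trimmed mean, and median signal per array ran from 27.5 to 37.3.

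Pooled over all arrays, no single gene was separated from the spread between arrays. None of the 13647 tested probe sets passed (limma), and 218 had an unadjusted p under 0.05, where 682 were expected by chance. The same count of 0 was found with replicate number as a fixed or random block, with replicate and serial set as blocks, with 9 pairs of replicate and set, and with arrays averaged to 3 against 3. An SA effect that differs between serial sets stays in the error of the pooled fit and of these blocks, though not of the averages. The counts of 0 therefore do not exclude an effect present in only some sets. Of all probe sets, 37.8% had the same sign of SA minus silwet in all 3 replicate numbers, against 25% by chance. This share fell to 23.4%, 19.1% or 21.2% when SA replicate 1, 2 or 3 of set 1 was left out, and was 48.0% without SA replicate 2 of set 3.

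Among 26 gene lists in the pooled comparison, genes of the plastid genome (49 tested, median log2 difference 0.09, adjusted p = 0.00185 by camera) and of the mitochondrial genome (10 tested, median 0.12, adjusted p = 0.0405) were shifted upward. Both calls were lost with an estimated correlation (adjusted p = 0.805 each), and no member of either list was called on its own. The plastid call also ended without silwet replicate 3 of set 1, 2 or 3, without SA replicate 1 of set 2 and without SA replicate 2 of set 3, with adjusted p = 0.0585, 0.0935, 0.177, 0.269 and 0.655. In the same order, its median fell to 0.056, 0.048, 0.020, -6.2e-05 and 0.022. The mitochondrial call ended when any of 11 of the 18 arrays was left out (adjusted p from 0.0531 to 0.221), and held only without silwet replicate 1 of set 1 or 2, silwet replicate 2 of set 2 or 3, or SA replicate 3 of any set. It also ended with 9 pairs as a block (adjusted p = 0.0557), with a pseudocount of 64 (0.0539), with arrays averaged (0.144), without probe sets of several transcripts (median 0.05, adjusted p = 0.165) and without replicate 1 (median 0.03, adjusted p = 0.178). With quantile normalization neither list passed (adjusted p = 0.0739 for both), nor with every probe set tested (0.152 and 0.144) or with array weights (0.649 and 0.672).

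The mean log2 ratio of 3′ to 5′ control signal was 0.29 ± 0.26 in SA and 0.39 ± 0.22 in silwet (SD, n = 9 each), a difference of -0.10 that lay within the spread between arrays (two-sided exact permutation test, p = 0.384).

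The arrays did not vary evenly. The first principal component held 45.0% of the variance, and the 3 SA arrays of serial set 1 lay between 52.8 and 67.7 on it, with every other array at 24.1 or below. SA was therefore also compared with silwet within each serial set, a choice made after these values had been seen.

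**Figure D1:**
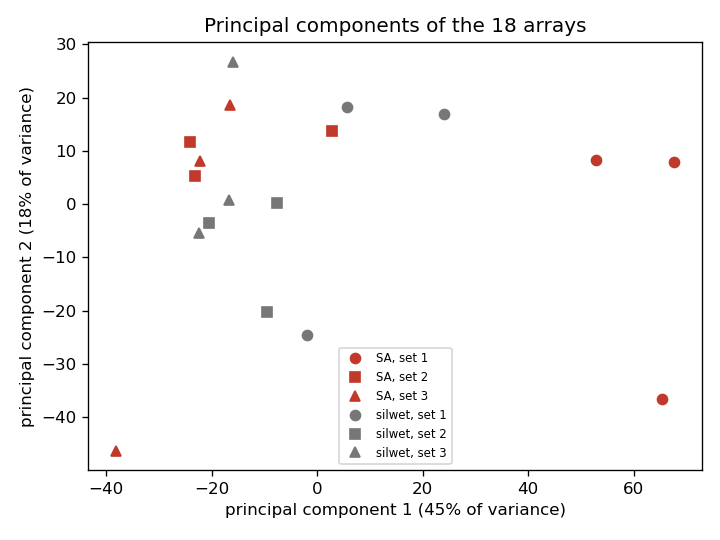
Scores of the 18 arrays on principal components 1 and 2 of log2(signal + 16), in arbitrary units, coloured by treatment and shaped by serial set. The 3 SA arrays of set 1 lie at 52.8 to 67.7 on component 1, and SA replicate 2 of set 3 lies at -46.2 on component 2.

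In set 1, the largest increases in SA included a hydroxylase of phenolic metabolism, both UGT76B1 and UGT73D1, and a beta-glucosidase. AT3G13610 (F6'H1), a hydroxylase of scopoletin synthesis, rose from a signal of 29.2 ± 32.5 to 587 ± 12.1 (SD, n = 3 each), a log2 fold change of 3.97 ± 0.48 (SE, limma adjusted p = 6.38e-05). UGT76B1, which glucosylates SA, rose from 120 ± 93.0 to 1324 ± 285 (log2 fold change 3.58 ± 0.51, adjusted p = 3.15e-04), and BGLU31, a beta-glucosidase, by 3.32 ± 0.46. UGT73D1, another glycosyltransferase, rose by 2.89 ± 0.43. The remaining 8 of the 12 largest increases carried only locus codes. They were AT5G22530 (3.42), AT3G21080 (3.25), AT5G44570 (3.18), AT1G10340 (3.11), AT1G08050 (3.01), AT5G43910 (2.89), AT5G39670 (2.78) and AT3G47540, of the chitinase family (2.78). Without replicate 1 the calls of AT5G44570 and AT1G10340 ended, at log2 fold changes of 2.48 and 2.79 (adjusted p = 0.0732 and 0.0628). Without replicate 2 that of AT5G44570 ended, at 3.18 (adjusted p = 0.119). A fit without a replicate number has fewer arrays in each cell, so a call can end there without a smaller fold change.

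The largest decreases in set 1 were smaller. AT5G62360, of the invertase and pectin methylesterase inhibitor family, fell from 725 ± 214 to 143 ± 73.3 (log2 fold change -2.28 ± 0.29, adjusted p = 1.26e-04). AT4G24350 fell from 150 ± 44.7 to 27.7 ± 12.3 (-1.93 ± 0.22, adjusted p = 4.18e-05). TBL26, a cell wall acetyltransferase homologue, fell by 1.69 on the log2 scale. The other decreases were AT5G09570 (-1.80), AT3G26960 (-1.77), AT1G68600 (-1.75), AT1G78450 (-1.73), AT4G33660 (-1.65), AT4G28080 (-1.62), AT1G74940 (-1.61), AT3G15570 (-1.60) and AT1G78020 (-1.53). The call of AT4G28080 (adjusted p = 0.0487) ended on leaving out any of 14 of the 18 arrays in turn, with adjusted p from 0.0511 to 0.225, and also with a pseudocount of 1 (adjusted p = 0.0530) and with every probe set tested (adjusted p = 0.0765). Without replicate 1, that call ended with adjusted p = 0.285. Without replicate 2 or 3, the calls of AT4G28080, TBL26, AT1G78450 and AT1G78020 ended (adjusted p from 0.0885 to 0.148), and without replicate 2 that of AT1G74940 (adjusted p = 0.103). The call of TBL26 ended without silwet replicate 2 or 3 or SA replicate 3 of set 1 (adjusted p up to 0.0877), and those of AT1G78450 and AT1G78020 without silwet replicate 1 or SA replicate 2 or 3 of set 1 (adjusted p from 0.0513 to 0.0652).

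In all, 928 probe sets were higher and 825 lower in SA in set 1, of which 478 and 214 changed at least 2-fold. With exactly 1 gene were 493 of the higher and 436 of the lower. The median difference over all tested probe sets was -0.11. With the 9 pairs of replicate and set as a block, the counts were 1636 and 2178. The lower count fell to 506, 406, 516 and 357 without silwet replicate 1, silwet replicate 2, SA replicate 1 and SA replicate 3 of set 1, and the higher count to 601 and 596 without silwet replicate 2 and SA replicate 3.

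**Figure D2:**
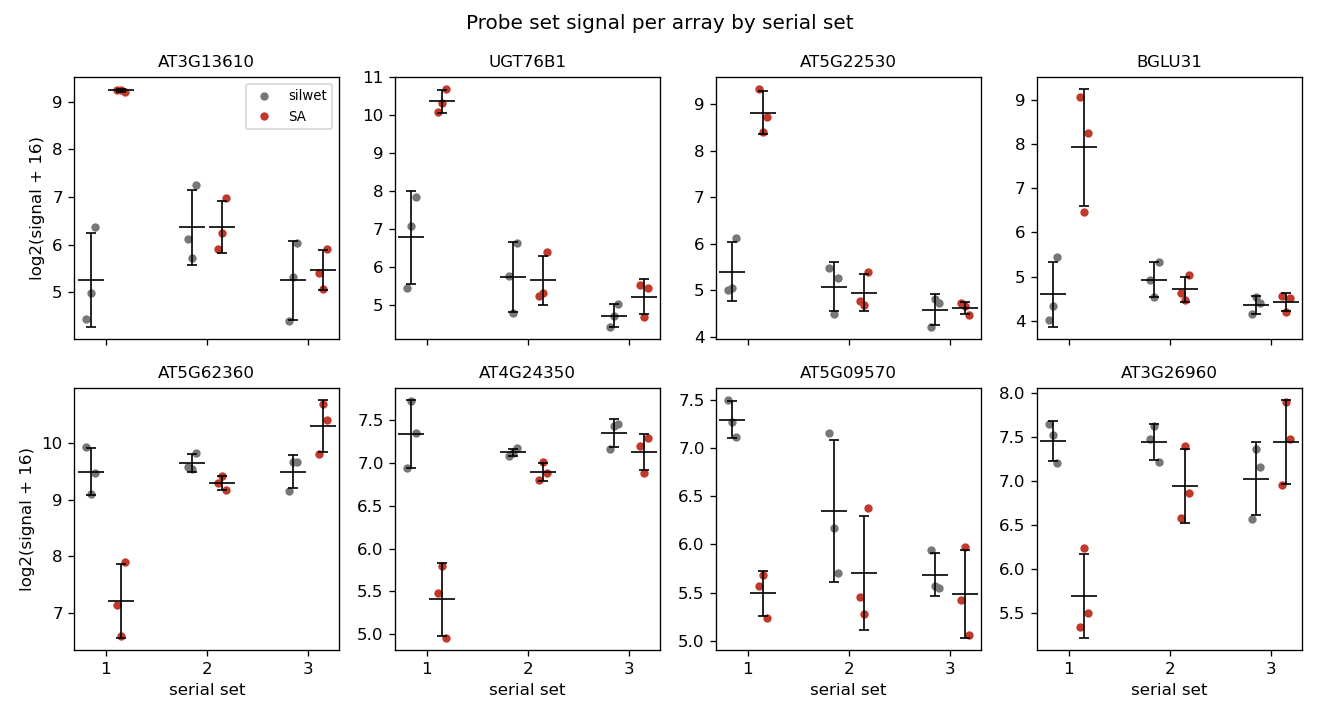
Log2(signal + 16) per array for the 4 largest increases (upper row) and decreases (lower row) in set 1, by serial set; points are arrays, bars the mean and SD of 3 arrays. In set 1 UGT76B1 differs by 3.58 log2 units between treatments, and in sets 2 and 3 by -0.07 and 0.50.

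In sets 2 and 3, no probe set passed (limma), with 233 and 187 at an unadjusted p under 0.05, where 682 were expected. This fit did not use the pairs of SA and silwet arrays, which deviated together. Its error may therefore be too large, but with the 9 pairs as a block there was still no probe set called in either set. A response in these sets is not excluded by this. The SE of a log2 difference in one set had a median of 0.22. The 12 genes with the largest increase in set 1 lay between -0.22 and 0.36 in set 2 and between -0.54 and 0.50 in set 3. The 12 with the largest decrease lay between -0.65 and 0.93 in set 2, with AT4G28080 highest, and between -0.32 and 0.80 in set 3, with AT5G62360 highest. The difference itself was tested. The F test called 481 probe sets whose SA effect differed between sets, and 1084 differed between set 1 and the mean of sets 2 and 3, 669 upward and 415 downward. With the 9 pairs as a block these counts were 2485 and 2988. When sets were redrawn within treatment and replicate number, 10 of 100 draws, the real one included, gave as many by the F test, and 11 of 100 gave as many as 1084 for any 1 set. The design puts the 3 SA arrays of set 1 together in some set in 11.1% of such draws, so these shares could not be expected under 0.05. Of the named genes, all 12 of the largest increases and 10 of the 12 largest decreases were among the 1084, without TBL26 (adjusted p = 0.105) and AT4G28080 (adjusted p = 0.0605). The F test called 11 of the 12 increases, without AT5G44570 (adjusted p = 0.0989), and 6 of the 12 decreases. These genes were chosen for their large values in set 1, which enter both tests, so their calls are no separate support for a difference. The count of 1084 fell to 568 and 593 without silwet replicate 2 and SA replicate 3 of set 1. The F test count fell to between 156 and 218 without silwet replicate 1 or 2 or SA replicate 1 or 3 of set 1. It fell to between 282 and 316 without silwet replicate 1 or SA replicate 1 or 2 of set 2, or without silwet replicate 2 or 3 or SA replicate 3 of set 3.

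**Figure D3:**
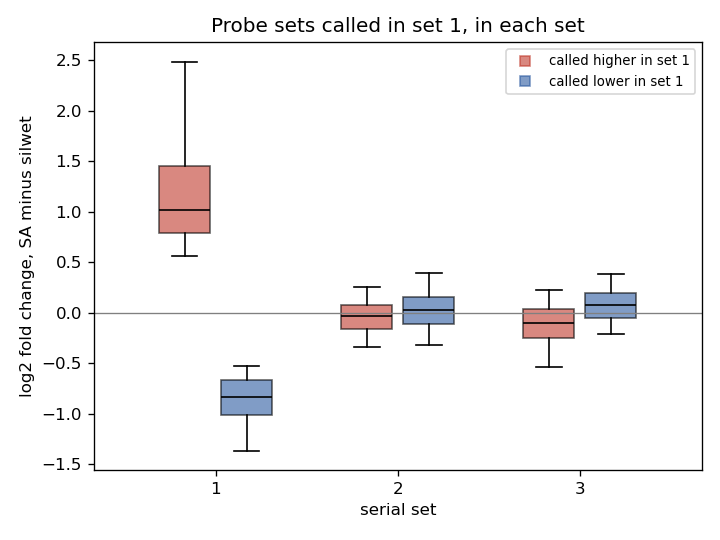
Log2 fold change, SA minus silwet, in each serial set for the 928 probe sets called higher and the 825 called lower in set 1; boxes show quartiles and median, whiskers the central 90 percent. Medians of the higher group are 1.01 in set 1, -0.04 in set 2 and -0.11 in set 3.

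Of 3 tested members of the list of SA synthesis, signalling and conjugation, UGT76B1 and SAG101, a partner of EDS1 in immune signalling, rose in set 1 (SAG101 by 1.12 ± 0.24, adjusted p = 0.00620), and both were also called when adjusted over the list alone. The SAG101 call ended without replicate 1 (adjusted p = 0.0845) and without replicate 3 (adjusted p = 0.0615). BSMT1, which methylates SA, was at -0.04 ± 0.55. Of 3 tested WRKY factors, WRKY53 rose by 1.52 ± 0.47 (adjusted p = 0.0420), and 2 were called when adjusted over the list alone. The WRKY53 call ended without silwet replicate 1 or 2 or SA replicate 1 or 3 of set 1, silwet replicate 2 or SA replicate 3 of set 3, or SA replicate 1 of set 2 (adjusted p from 0.0511 to 0.183), and also with a pseudocount of 1 (adjusted p = 0.0614), with every probe set tested (adjusted p = 0.0658) and without replicate 1, 2 or 3 (adjusted p = 0.254, 0.0665 and 0.0990). WRKY6 was at 1.12 ± 0.41, with adjusted p = 0.0833 unblocked and 0.00223 with the pairs as a block, and WRKY22 at 0.06 ± 0.19. Neither immune receptor list member passed. BIK1, a receptor-associated kinase, was at 0.89 ± 0.35 (adjusted p = 0.114, and 0.0110 with the pairs as a block), and EFR, the receptor of bacterial EF-Tu, at 0.17 ± 0.21. Adjusted over the list alone, 1 of the 2 was called.

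Of 4 tested detoxification enzymes, GRX480 (ROXY19), a glutaredoxin that binds TGA factors, rose by 2.50 ± 0.42 (adjusted p = 0.00107), and 2 were called when adjusted over the list alone. The transporter DTX3 (AT2G04050) was at -1.16 ± 0.43, UGT73B5 at 0.57 ± 0.28 and GSTU25 at -0.30 ± 0.27. With the pairs as a block, adjusted p was 0.00607 for DTX3 and 0.0171 for UGT73B5. The family of UDP-glycosyltransferases, 25 tested, had 2 members higher and 2 lower, among them UGT76C2 at -0.98 ± 0.22, and camera did not call it (adjusted p = 0.893).

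Of 5 tested genes of endoplasmic reticulum folding and secretion, 2 rose, both also when adjusted over the list alone, with a list median of 0.53 (adjusted p = 0.0171 by camera, and adjusted p = 0.609 with an estimated correlation). They were ERDJ3B, a luminal co-chaperone (1.26 ± 0.27), and SEC61A (AT2G34250), a translocon subunit (0.60 ± 0.19), whose call ended on leaving out any of 10 of the 18 arrays in turn (adjusted p from 0.0508 to 0.180), with every probe set tested (adjusted p = 0.0606) and without replicate 1, 2 or 3 (adjusted p = 0.115, 0.241 and 0.155). The ERDJ3B call ended without replicate 1 (adjusted p = 0.0850) and without replicate 2 (adjusted p = 0.0532). CRT1b, a calreticulin, and CNX2 (AT5G07340), a calnexin, were at 0.53 ± 0.30 and 0.50 ± 0.29, with adjusted p of 0.0114 and 0.0414 with the pairs as a block. Of 14 tested chaperone and export proteins, 2 rose, including DER1, a derlin of protein quality control (0.99 ± 0.15, adjusted p = 4.98e-04), and the family median was 0.29 (adjusted p = 0.0171, and adjusted p = 0.609 with an estimated correlation). Of 10 tested mitochondrial respiration proteins, IDH-VI (0.92 ± 0.19) and NDB2, an NAD(P)H dehydrogenase (1.14 ± 0.28), rose, with a median of 0.30 (adjusted p = 0.0171, and adjusted p = 0.609 with an estimated correlation). The respiration call also ended with every probe set tested (adjusted p = 0.156), with array weights (adjusted p = 0.0819) and without replicate 1 (median 0.07, adjusted p = 0.123), and the chaperone and export call without replicate 2 (adjusted p = 0.0590). All 3 calls were lost without silwet replicate 1 of set 1 (adjusted p = 0.0674), and both endoplasmic reticulum calls without SA replicate 3 of set 1 (adjusted p = 0.0692).

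Aliphatic glucosinolate synthesis had 2 tested members, and both fell, also when adjusted over the list alone: UGT74C1 (AT2G31790), a glucosyltransferase, by 1.28 on the log2 scale (adjusted p = 0.00219), and BCAT4, an aminotransferase of methionine chain elongation, by 0.94 (adjusted p = 0.0354). The UGT74C1 call ended without replicate 3 (adjusted p = 0.0551). The BCAT4 call ended without silwet replicate 2 or 3 or SA replicate 2 or 3 of set 1 (adjusted p from 0.0621 to 0.144), with every probe set tested (adjusted p = 0.0527) and without replicate 2 or 3 (adjusted p = 0.238 and 0.311). Of 13 trichome birefringence-like proteins 4 were lower and of 13 serine carboxypeptidase-like proteins 4 were lower and 2 higher, and camera called neither family (adjusted p = 0.258 each).

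No member passed in the lists of jasmonate response, photosynthesis, auxin response, clock, reference genes and seed, flower and root markers. THI2.1, a thionin, was at -0.86 ± 0.41 (adjusted p = 0.196, and 0.0149 with the pairs as a block), PDF1.2b at -0.65 ± 0.56 and PDF1.2, both defensins, at -0.56 ± 0.60. Photosynthetic RCA, LHCB4.2 and LHCB4.1 were at -0.34 ± 0.22, -0.18 ± 0.30 and -0.13 ± 0.23. GH3.3, an auxin-conjugating enzyme, was at 0.97 ± 0.64 (adjusted p = 0.0228 with the pairs as a block), WES1 at 0.28 ± 0.32 and IAA29 at 0.02 ± 0.21. The clock gene GI was at -0.92 ± 0.42 (adjusted p = 0.168, and 0.0423 with the pairs as a block), and was called when adjusted over its list alone, in which it was the 1 tested member. The reference gene TIP41 (AT4G34270) was at -0.02 ± 0.15, with its sign turned under quantile and 75th percentile scaling, and the root marker PYK10 at -0.02 ± 0.42, with its sign turned under the latter.

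In set 3, camera called plastid-encoded genes higher (median 0.32, adjusted p = 2.95e-12) and endoplasmic reticulum folding genes lower (median -0.41, adjusted p = 0.00969). Both calls ended with an estimated correlation (adjusted p = 0.760), with array weights (adjusted p = 0.790 and 0.177) and without SA replicate 2 of set 3 (medians 0.095 and -0.19, adjusted p = 0.468 and 0.243). The second also ended without silwet replicate 3, SA replicate 1 or SA replicate 3 of set 3 (adjusted p = 0.140, 0.0659 and 0.0538), and without replicate 3 of all sets (adjusted p = 0.110).

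The ubiquitin control ratio went with set 1. On its 3 SA arrays the log2 ratio of 3′ to 5′ signal was 0.706 to 1.12, below the 1.15 to 1.81 of the other 15 arrays. The actin and GAPDH ratios of these arrays lay inside the range of the others.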

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

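The within-set comparisons, and the tests of RNA quality, of swapped arrays of the splits of the pooled probe set count, of the draws for the F test and for the largest of the 3 sets, and of all draws within replicate numbers, were chosen only after the results had been seen.

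The SA effect differed between serial sets for 481 probe sets by the F test, and for 1084 between set 1 and the mean of the other sets. One deviant array or the scaling does not account for the calls in set 1, since leaving out any 1 of its 6 arrays gave at least 54.4% of their number, and the other scalings at least 98.3%. A swap between treatments in sets 2 and 3 would need a silwet array there with values like the SA arrays of set 1. In the mean of genes called higher minus lower in set 1, the lowest of these SA arrays lay 14.9 SD above the highest silwet array of sets 2 and 3. The genes were chosen in set 1, so its SA arrays score high by choice. An exchange of labels within set 1 would leave the gap alike, so this score cannot test it. That exchange, an unpaired wrong label, and SA arrays of sets 2 and 3 from untreated plants stay open. RNA quality stays open too: all 3 SA arrays of set 1 lay inside the range of the others in mean 3′ to 5′ ratio, but outside it for ubiquitin alone. No biological explanation was tested, because the labels do not say what the sets are; a harvest time after treatment that differs between sets is a candidate explanation the labels cannot test.

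Probe sets called higher in set 1 had a median of -0.11 in set 3, and 69.2% of them lay below 0. Camera with a preset correlation gave p = 1.72e-07 for this shift, and p = 0.279 with an estimated correlation. As far as quantile normalization removes them, differences in signal distribution between arrays do not account for the shift, as the median was then -0.0871. Without SA replicate 2 of set 3 it was -0.0451, smaller but still below 0 and between the bounds written beforehand, so the part of that array stays open. No biological explanation was tested.

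The SA array of replicate 2 in set 3 stood apart from the other 8 SA arrays in its signal distribution. Its mean signal was 156.9, against 131.0 to 141.0 on the others. Its 75th percentile was 96.4, against 108.2 to 118.1, its 99th percentile 2520, against 1540 to 1923, and its highest signal 8935, against 3748 to 5627. Without it, set 1 called 1059 probe sets higher and 1067 lower, sets 2 and 3 still 0, and 1287 differed between set 1 and the others.

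SA replicate 1 of set 3 had an actin log2 3′ to 5′ ratio of -1.80, against -0.933 to -0.131 on the other SA arrays. Among silwet arrays, replicate 1 of set 3 was lowest in AT3G26960, at 6.57 in log2(signal + 16). Silwet replicate 1 of set 2 was lowest in AT4G28080, at 6.99, and in GI, at 7.09. Silwet replicate 3 of set 1 was highest in ERDJ3B, at 9.70. Such gaps were found in 9 of 126 groups, where chance gives about 1 in 20.

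The pooled count of 0 cannot differ from chance, as all 100 of 100 splits of 9 against 9 gave 0 or more, at most 1. The 2 lists called in the pooled comparison were matched by 72 of 100 splits, with up to 10 lists, so chance is not excluded. The splits of 9 against 9 did not keep the pairs of SA and silwet arrays. For set 1, the real split called 1753 probe sets and the highest of the others 1, and the 10 splits are too few for a share under 0.05; 1 of the 10 was as large. Its 3 called lists were matched by 5 of 10 splits, with up to 7. In sets 2 and 3 the real splits called 0, which 10 of 10 splits match in either set, again too few splits for a share under 0.05, with at most 0 in set 2 and 309 in set 3. The split with 309, the highest of the 10, put silwet replicate 1 with SA replicates 1 and 3. SA replicate 2, which stood apart in its signal distribution, was on the other side. The cause of this count was not tested. Each set holds 1 array of each replicate number, so sets were drawn anew within treatment and replicate number. As many as the real 1084 were called for set 1 in 5 of 100 draws, the real one included, and for the largest count over the 3 sets in 11 of 100, with up to 3452. The F test called as many as the real 481 in 10 of 100, with up to 2853. The design puts 3 given arrays of different replicate numbers together in some set in 11.1% of such draws, however large their effect, and the count for set 1 does not allow for its choice. For a pattern that lies in 3 arrays, these draws therefore cannot give a share well under 0.05, and they do not decide on chance. Of the 11 draws that kept the 3 SA arrays of set 1 together, 10 called as many for the largest of the 3 sets, the real one included. The highest count of the other draws for the largest of the 3 sets was 1653, above the real 1084. A high count of this kind therefore did not need these arrays together. By the F test, the highest count of the other draws was 5, below the real 481. As the 3 arrays were singled out from the data, the share of 10 in 11 only restates that they stood apart. Draws that did not keep the replicate numbers gave as many in 2 of 100, with up to 3116 for set 1 or the largest of the 3 sets and 2154 for the F test, and decide nothing, since they break that order.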

How the results depend on the processing

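The tests within sets, those of the differences between sets and the alternatives for single gene lists other than endoplasmic reticulum folding were chosen after the data had been seen, as was the second group of control probe sets. The 31 named genes called in set 1 kept their sign in all 1014 values under the alternatives, and passed in 938 of them. They came from the largest increases and decreases and from the lists fixed beforehand. Other named family members and the genes under other observations were not included. The 31 were singled out by their calls in set 1, which favours a stable sign. With a block, without the variance trend or without an array of another set, the fold change in set 1 cannot move. Part of the 1014 signs was therefore fixed in advance. The 22 named genes not called had the other sign in 28 values, passed in 20 and were alike in 668. The number of arrays limits the precision, and weak signals near background lower the fold changes.

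Of 26 lists in the pooled comparison, 1 passed with a pseudocount of 64, in the upper 40% by mean, with array weights, with 9 pairs as a block, with arrays averaged and without probe sets of several transcripts; 0 passed with quantile normalization, without a filter and with an estimated correlation. With array weights, camera ranked endoplasmic reticulum folding genes below other genes in the pooled comparison (adjusted p = 0.919), with their median still above 0 at 0.039. In set 1, the higher count was 1636 with 9 pairs as a block and 478 at 2-fold or more, and the lower count 1591 with array weights, 2178 with the pairs and 214 at 2-fold or more. The count for set 1 against the other sets was 2681 with array weights, 1708 with a replicate block, 2988 with the pairs and 714 at 2-fold or more. The F test count was 1776 with array weights, 1050 with a replicate block, 2485 with the pairs and 931 with a random replicate block. Of lists in set 1, 0 passed with an estimated correlation. Of lists in set 3, 6 passed in the upper 40% by mean, 5 with the pairs, 0 with array weights and 0 with an estimated correlation. The GAPDH ratio alone differed by 0.00307. The cause of these changes was not tested.

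With single arrays or replicate numbers left out, pooled lists ran from 0 to 5, the share with the same sign from 19.1% to 48.0%, set 1 higher counts from 301 to 1059 and lower counts from 115 to 1067. The count for set 1 against the other sets ran from 117 to 1321, the F test count from 19 to 663, lists in set 1 from 0 to 5 and lists in set 3 from 0 to 4.

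Signs turned for uncalled genes near 0. AT4G34270 was at 0.012 with quantile normalization and 0.014 with 75th percentile scaling, PYK10 at 0.0066 with the latter, and WRKY22 at -0.0076 with array weights. With single arrays or replicate numbers left out, WES1 ran from -0.032 to 0.52, IAA29 from -0.11 to 0.26, LHCB4.2 from -0.46 to 0.058, LHCB4.1 from -0.28 to 5.07e-04, AT4G34270 from -0.13 to 0.11, BSMT1 from -0.32 to 0.42, PYK10 from -0.52 to 0.25 and WRKY22 from -0.090 to 0.23.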

Other observations

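The within-set comparisons were chosen after the pooled result had been seen, and the genes of this paragraph, except CML37 and PUB24, after their own values. Beyond the lists, set 1 SA arrays were higher in the heat shock proteins Hsp70-2 (log2 fold change 2.75, adjusted p = 1.33e-04) and Fes1A, an Hsp70-binding factor (2.32, adjusted p = 1.12e-06). CCR2, a cinnamoyl-CoA reductase of phenolic metabolism, rose by 2.32, CML37, a calmodulin-like calcium sensor, by 2.12, and MSRB9, a methionine sulfoxide reductase, by 2.05. The U-box ubiquitin ligase PUB24 rose by 1.75. MSRB5, another methionine sulfoxide reductase, fell by 1.42. In sets 2 and 3 all of these lay between -0.43 and 0.30, and none was called there.

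Several families held members that moved apart in set 1. The tetraspanin TET8 rose by 1.35 and TET3 fell by 0.74. The cytochrome P450 CYP71B23 rose by 1.26 and CYP71B34 fell by 0.87. Of 9 tested vacuolar sorting proteins 2 rose, with VPS60.1 at 1.28, and of 8 tested PRA1 proteins of vesicle traffic 2 rose, with PRA1.G2 at 0.66. Camera called neither family (adjusted p = 0.0968 and 0.357).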
